A study of Mus musculus with 36 samples.

How the data were processed

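RNA was sequenced from ribosome pull-downs of mouse brain tissue and from the unbound RNA left behind by them. In translating ribosome affinity purification (TRAP), a green fluorescent tag on the ribosomal protein L10a, expressed in 1 cell type, lets antibodies collect that cell type's ribosomes and the RNA on them. Per the labels, 1 set of mice carried the tag in microglia (Cx3cr1CreErt2 with a Cre-dependent eGFP-L10a, induced by tamoxifen at 4 to 6 weeks of age) and a designer receptor, Chrm3 or Chrm4, under a Camk2a-tTA driver of forebrain neurons. These animals received clozapine-N-oxide (CNO), which activates such receptors, or saline for 2 h. In the other set the tag was expressed in D1 neurons (Drd1-eGFPL10a), and the animals were labelled as controls or Il34 knockouts. The source label reads Il34-/- for the controls too, and adds Drd1-Cre for the knockouts alone. Libraries were made with the NuGEN Ovation V2 and TruSeq kits and read on a NextSeq 500 for 75 cycles from 1 end, per the labels.

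The deposited values are RPKM (reads per kilobase of gene, scaled to the size of the library), calculated by the authors, in 1 table of 20 libraries and 1 of 15. The submitters' processing notes name bcl2fastq, TopHat2 2.1.0, HTSeq 0.6.0 and DESeq2, with the genome build mm9. They state neither what each tool was used for, nor the annotation, the gene lengths or which reads count towards the size of the library. All 35 columns were joined to samples by the group that the headings give. The columns carry no replicate numbers, so a library's number here is only its place within its group, and no pull-down could be matched to its own unbound RNA. 1 sample of striatal single nuclei was not analysed here. In the table of 20 libraries, 147 of 22707 lines hold no values and were left out.

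Whole read numbers behind the RPKM were recovered from the smallest steps between a gene's values. They came out whole within 0.0001 reads for 100% of 18102 and 18090 genes above 0 in 2 or more libraries, and in simulation 99.972% and 99.9889% of genes came back exactly. The recovered totals in genes ran from 12.1 to 109 M reads per library in the table of 20 (a 8.98-fold range) and from 11.3 to 41.1 M in the table of 15 (3.64-fold). Reads without molecular identifiers are not independent molecules, so these depths bound counting error only.

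Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend) on log2(RPKM + 1), as deposited and without rescaling. Genes needed a mean of at least 1 RPKM over the libraries of the fit. Tests were two-sided and called at a Benjamini-Hochberg adjusted p under 0.05. Chance alone gives between 493 and 586 genes of a comparison an unadjusted p under 0.05, depending on the number tested. The 10 microglial pull-down libraries were fitted together, as were the 10 unbound libraries of the same mice, so that groups of 2 share the spread of all. Differences between fractions used all 20, and in the D1 mice the fits held 7, 8 or 15 libraries. The 11 comparisons and 31 gene lists were fixed before the data were examined. Lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and on ranks. For each list, members past adjusted p 0.05 were counted over all genes tested and adjusted over the list alone. Fold changes are 2 to the power of the log2 change of RPKM + 1, log2 changes are followed by their standard error, and RPKM values are group means ± SD.

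Genes were named by a rule also fixed in advance. It takes the 8 largest rises and 8 largest falls past the threshold with at least 2 RPKM in the higher group, up to 4 members of each list with the smallest unadjusted p, and a fixed set of receptor, ligand and marker genes. Arl5b, Eya1, Prl and Gh, and the values of single libraries, were chosen after their values were seen. Positions are from GENCODE release M21 on GRCm38, joined by Ensembl identifier for 92.8% and 92.2% of the lines with values, not from the authors' mm9 annotation.

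The same fits were tested on simulated tables of the same depth and spread in which 200 genes were changed 2-fold or 4-fold. In the comparison of CNO with saline in Chrm3 microglia, 23% and 80% of them were called, and 66% and 98% in the unbound RNA. For the Chrm4 mice these shares were 13% and 60% in microglia, 69% and 91% in unbound RNA. In the D1 mice they were 90% and 95% in D1 neurons, 95% and 100% in unbound RNA. They were lowest for Chrm3 against Chrm4, with 2% and 38%. Between 2.67% and 6.98% of the calls were genes that had not been changed. The changed genes had a mean of at least 2 RPKM, and all genes were drawn independently of one another. These shares therefore hold for 200 changes without correlation between genes, and may differ where genes vary together or fewer change.

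Alternatives fixed in advance were a pseudocount of 0.1, no minimum, a minimum of 5 RPKM, quantile and median-ratio scaling, array weights, fits holding only the compared groups, and leaving out each library in turn. Added after the data were seen were sex (read from Ddx3y), a class of sequencing depth, limma voom on the recovered reads, leaving out libraries with pituitary hormone RNA, and the list tests under every setting. Figures were drawn with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.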

Results

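Microglial RNA was compared between mice given CNO or saline and labelled as carrying a designer receptor for CNO in forebrain neurons. RNA of D1 neurons and of the unbound tissue was compared between animals labelled control and Il34 knockout. The receptor Chrm3 is of the kind that excites neurons and Chrm4 of the kind that silences them. The words activation and silencing below follow the labels. In the Chrm3 mice there were 3 libraries for each of saline and CNO, from the microglial pull-down and again from the unbound RNA. In the Chrm4 mice there were 2 for each. No group was labelled as receiving CNO without a designer receptor, so effects of CNO itself and of the receptor cannot be told apart within a line. The D1 line gave 4 control and 3 knockout pull-down libraries, and 4 and 4 unbound libraries. Depth in genes was 22.6 to 96.2 M reads (saline) and 14.1 to 107 M (CNO) in the Chrm3 pull-downs, and 22.8 to 75.7 M and 12.1 to 97.1 M in their unbound RNA. In the Chrm4 mice it was 22.7 to 22.7 M and 19.9 to 20.1 M in pull-downs, but 20.5 to 23.6 M (saline) and 106 to 109 M (CNO) in unbound RNA. D1 pull-downs held 24.5 to 41.1 M and the unbound libraries of that line 11.3 to 29.1 M. Both sexes were present in every group by the level of Ddx3y, a gene of the Y chromosome.

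Which RNAs did the microglial pull-down enrich? In saline mice the pull-down was dominated by genes of microglia, the resident immune cells of the brain, and held less RNA of every neuronal type measured. Ctss, a lysosomal protease, stood at 2364 ± 483 RPKM in the pull-down and 12.5 ± 3.93 in unbound RNA (SD, n = 5 each), 185-fold higher (log2 7.53 ± 0.17). Fcer1g (1136 ± 152 against 5.87 ± 1.10 RPKM) and Tyrobp (1259 ± 165 against 7.71 ± 2.28), partner chains of immune receptors, were 171-fold and 152-fold higher. The complement subunits C1qc and C1qb were 168-fold and 149-fold higher, the macrophage lysozyme Lyz2 141-fold, Ly86 128-fold and the calcium-binding Aif1 122-fold. Cx3cr1, the receptor whose promoter drove the tag, reached 225 ± 35.7 against 1.29 ± 0.198 RPKM (98.4-fold).

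All 30 homeostatic microglia genes rose, over all genes and adjusted over the list alone, with a median log2 of 5.98 ± 1.08 (SD over genes). The list passed with an estimated correlation too (adjusted p = 0.0224). Among them were P2ry12, the receptor that draws microglial processes to ADP (83.9-fold; chromosome 3, 59216272 to 59262871 of GRCm38), Csf1r, the survival receptor for the ligands Csf1 and Il34 (63.2-fold), and the integrin Itgam (67.0-fold). Entpd1, the ectoenzyme that degrades extracellular ATP, rose 22.8-fold to 83.4 ± 19.8 RPKM, whereas Nt5e, which makes adenosine from AMP, fell to 0.565 of its unbound level. The adenosine receptors Adora1 (log2 -0.78 ± 0.19) and Adora2a (-1.46 ± 0.21) fell as well. All 24 process motility and adhesion genes were higher, 23 past the threshold, and 7 of 8 complement genes rose (adjusted p = 0.0478 and 0.0422 with an estimated correlation). Markers of perivascular macrophages, which share the Cx3cr1 promoter, rose in 9 of 10 cases, such as Cbr2 (log2 3.91 ± 0.23) and Lyve1 (6.39-fold), with adjusted p = 0.0631 with an estimated correlation. The chemokine, NF-kB and interferon lists rose (15 of 19, 9 of 12 and 11 of 13 members; adjusted p = 0.0631, 0.113 and 0.113 with an estimated correlation), as did disease-associated genes (10 of 16; 0.113 as adjusted p with an estimated correlation). Ribosomal protein genes rose in 52 of 81 cases, for example Rpl7 (2.73-fold), with adjusted p = 0.356 with an estimated correlation.

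Most neuronal and glial markers fell in the pull-down but did not vanish from it, and the neurofilament gene Nefl rose (log2 1.26 ± 0.13). Snap25, a synaptic vesicle fusion protein, fell from 2484 ± 383 to 561 ± 141 RPKM, the vesicle sensor Syt1 to 0.245 and the spiny neuron phosphatase inhibitor Ppp1r1b to 0.179 of the unbound level. Further falls were Nrgn (0.135), Mtap2 (0.141), Calb1 (0.161), the mitochondrial Chchd10 (0.107), the myelin gene Mbp (0.225) and the astrocyte glutamate transporter Slc1a2 (0.350). All 10 D1, 10 interneuron, 14 pan-spiny and 8 cortical neuron markers fell, as did 10 of 11 pan-neuronal, 13 of 14 astrocyte and 13 of 14 oligodendrocyte markers. Of these lists the interneuron markers passed with an estimated correlation (adjusted p = 0.0224), and for the others adjusted p = 0.113 to 0.221 with an estimated correlation. The D2, oligodendrocyte precursor, cAMP signalling, glutamate receptor, GABA receptor, potassium channel and respiratory chain lists fell as well (adjusted p = 0.0631 to 0.398 with an estimated correlation). The ATP and adenosine list rose, 8 of 15 members higher and 5 lower past the threshold (adjusted p = 0.113 with an estimated correlation). Of 11721 genes, 3743 were higher and 3890 lower. Quantile scaling, which moved the median of all genes from -0.03 to -0.17, gave 3170 and 4599.

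**Figure D1:**
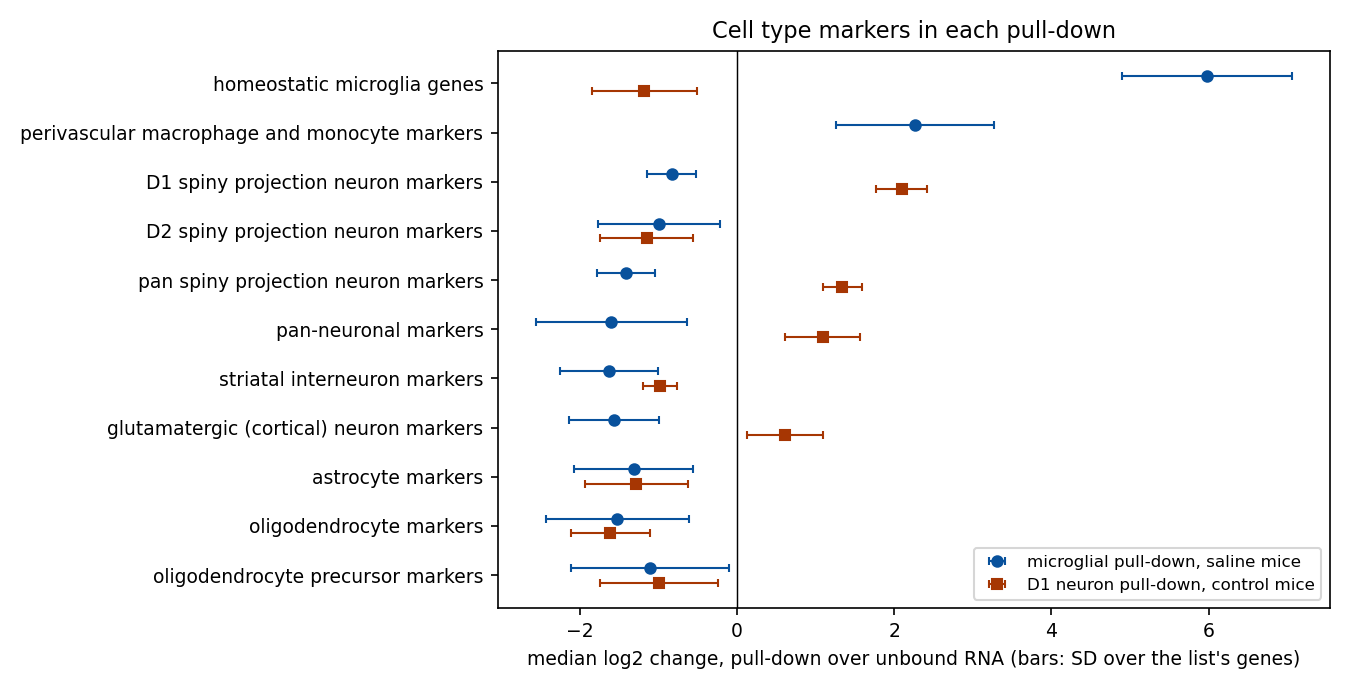
Median log2 change in the pull-down over unbound RNA for 11 lists of cell type markers; bars are the SD over a list's genes, circles the microglial pull-down of saline mice and squares the D1 pull-down of control mice. Homeostatic microglia genes lie at 5.98 in the first and -1.18 in the second.

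What did activating neurons through Chrm3 do to microglial RNA? Immediate early genes, transcribed within minutes of a stimulus, were far higher in the microglial pull-down 2 h after CNO. Nr4a1, an orphan nuclear receptor (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795), rose from 4.20 ± 0.940 to 55.9 ± 31.3 RPKM (SD, n = 3 each; log2 3.25 ± 0.41, adjusted p = 0.00945). The transcription factors Fosb (37.0 ± 25.3 against 1.74 ± 1.13 RPKM), Egr1 (log2 2.28 ± 0.30) and Egr2 (41.7 ± 25.7 against 2.90 ± 1.63), and Arc, a regulator of synaptic receptors (72.7 ± 39.7 against 6.32 ± 4.48), rose by log2 2.28 to 3.58 in all, with adjusted p between 0.00945 and 0.0241. For each of the 5, all 3 CNO libraries lay above all 3 saline libraries. Of the 32 measured members of the activity list 31 were higher, with a median log2 of 1.49 ± 1.15. Over all genes 5 rose, and 25 did adjusted over the list alone, among them Fos (18.7 ± 13.8 against 0.882 ± 1.10 RPKM), Npas4, Ptgs2, Bdnf and Homer1. This list passed with an estimated correlation (adjusted p = 0.0407).

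Genes for secreted attractants of immune cells were higher too. Ccl4 stood at 16.4 ± 4.76 against 3.13 ± 1.59 RPKM, Ccl3 at 91.8 ± 35.4 against 19.2 ± 3.95, Ccl2 at 15.6 ± 11.8 against 1.73 ± 1.97 and Ccl7 at 3.51 ± 2.74 against 0.136 ± 0.144. These 4 rose adjusted over the list alone but not over all genes (adjusted p = 0.0963 to 0.285), and the other 17 members of the chemokine list did not pass. The list passed (adjusted p = 5.30e-05, and 0.358 as adjusted p with an estimated correlation). In the plot of activity and chemokine genes, every CNO library of the Chrm3 pull-down lies above every saline library for all 4. NF-kB targets, 11 of 13 higher and none past the threshold alone, rose as a list with a median log2 of 0.45 (adjusted p = 0.151 with an estimated correlation), for instance Nfkbia, the pathway's own inhibitor (0.74 ± 0.27). Of 9 heat shock genes 8 were higher, and Hspa8 (0.72 ± 0.21), Dnaja1 (0.63 ± 0.20), Dnajb1 (0.84 ± 0.27) and Hsph1 rose adjusted over the list alone (list adjusted p = 0.151 with an estimated correlation).

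**Figure D2:**
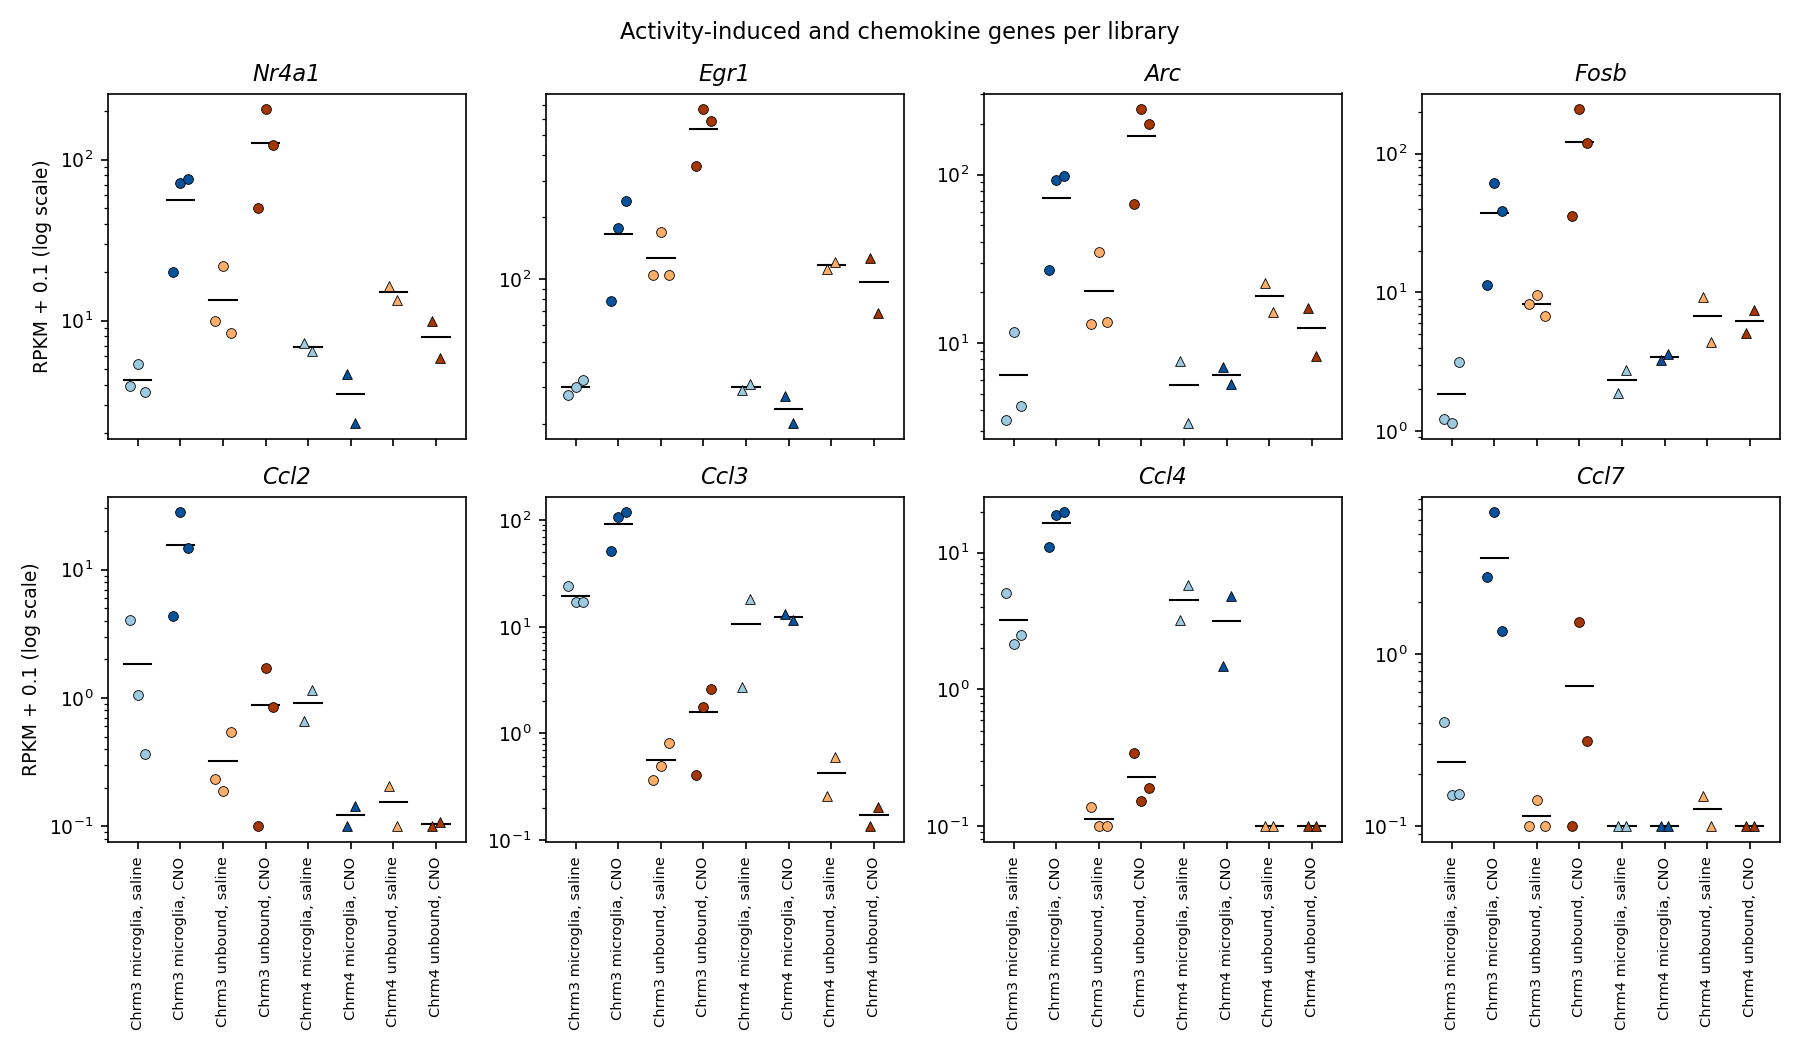
RPKM (+ 0.1, log axis) of 4 activity genes and 4 chemokine genes in each library of 8 groups; circles are Chrm3 and triangles Chrm4 mice, blue the microglial pull-down, orange unbound RNA, light saline, dark CNO and lines the means. Nr4a1 is at 55.9 RPKM in the Chrm3 CNO pull-down and 4.20 in saline.

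Glucocorticoid-responsive genes rose as a list but in both directions. Cdkn1a, a cell cycle inhibitor (0.84 ± 0.21), the clock gene Per1 (0.68 ± 0.22), Ddit4 and Nfkbia rose and Mt1, a metal-binding protein, fell (-0.75 ± 0.19), adjusted over the list alone. The list had adjusted p = 0.0152, and 0.609 as adjusted p with an estimated correlation. Disease-associated microglia genes fell as a list, 12 of 16 lower with none past the threshold, such as Cd9 (-0.58 ± 0.19) and Cst7 (-0.54 ± 0.23), with adjusted p = 0.688 with an estimated correlation. Neuronal and glial markers moved at the same time. All 14 pan-spiny markers were lower (median -0.46), including Pde1b (-0.72 ± 0.24) and Ppp1r1b (-0.71 ± 0.24), as were 13 of 14 oligodendrocyte markers, 13 of 14 astrocyte markers, 12 of 15 glutamate receptor genes and 55 of 82 ribosomal protein genes. None of these members passed alone, and the lists had adjusted p = 0.678 to 0.823 with an estimated correlation. Identity genes of microglia did not pass: P2ry12 was at 634 ± 89.3 against 624 ± 158 RPKM (95% interval of log2 -0.39 to 0.48), Csf1r at 252 ± 31.5 against 239 ± 54.7, Cx3cr1 at 220 ± 17.8 against 215 ± 43.0 and Entpd1 at 86.7 ± 13.4 against 83.0 ± 25.4. The receptor gene Chrm3 stood at 2.65 ± 1.18 against 0.660 ± 0.108 RPKM (adjusted p = 0.686).

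Of 11465 genes 5 passed, all higher, and 630 had an unadjusted p under 0.05, against 573 by chance. Without saline library 1, 2 or 3 the count was 0, 2 or 1, without CNO library 2 or 3 it was 0, and without CNO library 1, the weakest responder, it was 35 and included Fos, Ccl2, Ccl3 and Ccl4 (adjusted p = 0.000485, 0.0119, 0.0410 and 0.0277). The 5 genes then had adjusted p = 0.0590 to 0.181 where lost. The activity, heat shock and NF-kB lists passed without any of the 6 libraries. The chemokine list was lost without CNO library 2 (adjusted p = 0.122), pan-spiny markers without saline library 3 (0.143), and glucocorticoid genes without saline library 2 or CNO library 2 or 3 (up to 0.166). Disease-associated genes were lost without saline library 1 or 2 or CNO library 3 (up to 0.472), glutamate receptors and astrocyte markers without saline library 3 or CNO library 1 or 2 (up to 0.725 and 0.429), oligodendrocyte markers without saline library 3 or CNO library 2 (up to 0.538) and ribosomal genes without saline library 1 or 3 or CNO library 1 (up to 0.667).

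What did silencing neurons through Chrm4 do to microglial RNA? No gene passed, and the activity genes did not pass as a list (19 of 32 higher, median 0.10; adjusted p = 0.734). Nr4a1 stood at 3.39 ± 1.67 RPKM after CNO and 6.78 ± 0.623 after saline (SD, n = 2 each), and Fos at 0.580 ± 0.0849 against 0.679 ± 0.235. Mitochondrial respiratory chain genes fell as a list (50 of 73 lower, median -0.13; adjusted p = 0.698 with an estimated correlation), for instance the cytochrome oxidase subunit Cox7c (100.3 ± 2.43 against 158 ± 5.20 RPKM), as did ribosomal protein genes (59 of 82 lower; adjusted p = 0.971 with an estimated correlation), for instance Rpl36 (103 ± 0.783 against 149 ± 0.529). D2 neuron markers fell as a list (6 of 7 lower, adjusted p = 0.698 with an estimated correlation). Penk, the opioid peptide precursor, was at 107 ± 16.8 against 179 ± 20.7 RPKM. All 8 D2 markers measured in unbound RNA of these mice were lower too (median -0.29). Neuronal RNA carried into the pull-down therefore cannot be told apart from a change in microglia. Oligodendrocyte precursor markers rose (7 of 8 higher; adjusted p = 0.698 with an estimated correlation), with the growth factor receptor Pdgfra at 2.29 ± 0.334 against 0.385 ± 0.305 and the matrix protein Tnr at 3.33 ± 1.08 against 1.26 ± 1.04. No member of these 4 lists passed over all genes or adjusted over the list alone.

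Other values of microglial genes did not pass. P2ry12 was at 627 ± 34.9 against 639 ± 60.8 RPKM, Csf1r at 239 ± 18.6 against 219 ± 54.0, Cx3cr1 at 193 ± 10.6 against 239 ± 26.3, Entpd1 at 66.9 ± 5.79 against 83.9 ± 16.7, and Vav1, an exchange factor for Rac, at 24.8 ± 2.70 against 14.4 ± 0.547. The receptor gene Chrm4 was at 2.06 ± 0.434 against 2.55 ± 2.22. Cd74, of antigen presentation, was at 28.6 ± 0.0254 against 12.6 ± 5.36. Ttr, a thyroid hormone carrier made by the choroid plexus, rose adjusted over its list of 3 alone (37.7 ± 44.8 against 1.67 ± 0.986), with 1 CNO library at 69.4 RPKM. By limma 0 of 11465 genes passed and 433 had an unadjusted p under 0.05, and voom on the recovered reads gave 0 and 210. D2 markers were lost without saline library 1 or 2 or CNO library 1 (up to 0.305), precursor markers without saline library 2 or CNO library 2 (up to 0.692), and ribosomal genes without saline library 1 or CNO library 2 (up to 0.169).

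Did the microglial responses to the 2 receptors differ? The activity genes rose more after CNO in Chrm3 than in Chrm4 mice, a difference lost with an estimated correlation (adjusted p = 0.209 with an estimated correlation). The difference of the changes was 4.12 ± 0.65 on the log2 scale for Nr4a1, 2.64 ± 0.48 for Egr1 and 3.92 ± 0.79 for Egr2, with a median of 1.27 ± 1.41 over 32 genes, 28 of them positive. Of these 15 passed adjusted over the list alone and 0 over all genes. Ccl4 (2.61 ± 0.60) and Ccl2 (3.34 ± 0.89) differed adjusted over the chemokine list alone, whose median was 0.32, and the heat shock list (median 0.34; Dnajb1 1.24 ± 0.42) and the glucocorticoid list (0.43) were also more positive in Chrm3 mice (adjusted p = 0.667 for these 3 lists with an estimated correlation). Astrocyte markers were more negative (-0.42; adjusted p = 0.748 with an estimated correlation). By limma 0 of 11465 genes passed and 452 had an unadjusted p under 0.05 (voom 0 and 624), but 12 passed without Chrm3 CNO library 1, among them Nr4a1 (adjusted p = 0.000487), Egr1 (0.000805) and Egr2 (0.00594). The activity list passed without any 1 library. Lost were the chemokine list without Chrm3 CNO library 2 (0.0634), heat shock without that library or Chrm4 CNO library 1 (up to 0.0634), glucocorticoid without Chrm3 CNO library 2 or 3 or Chrm4 saline library 1 (up to 0.114), and astrocyte markers without Chrm3 saline library 3, Chrm3 CNO library 1 or 2, Chrm4 saline library 2 or Chrm4 CNO library 2 (up to 0.501).

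What did Chrm3 activation do to the unbound RNA, which is mostly neuronal? Activity genes rose far more than any other group, and 1 gene outside them, Plxdc2, gave the smallest p. Npas4, a neuron-specific activity factor, rose from 3.13 ± 1.56 to 195 ± 179 RPKM (log2 4.78 ± 0.80) and Fos from 2.56 ± 2.16 to 105 ± 85.5 (4.57 ± 0.65; SD, n = 3 each, adjusted p = 0.0236 and 0.0118). Egr2 rose 14.3-fold, Fosb 10.8-fold, Egr4 10.6-fold, Btg2 8.61-fold, Nr4a1 8.36-fold, Nr4a3 7.07-fold, Fosl2 6.87-fold, the neurotrophin gene Bdnf 4.11-fold and Egr3 3.35-fold. All 30 measured activity genes were higher (median 2.11 ± 1.17), 23 past the threshold over all genes and 30 adjusted over the list alone (list adjusted p = 0.0941 with an estimated correlation). Rgs2, which curbs Gq signalling, rose from 82.7 ± 3.75 to 446 ± 311 RPKM, Crem, a cAMP-responsive factor, 1.94-fold, Ier3 2.34-fold and the chaperone Dnajb1 2.28-fold. 6 of 10 heat shock genes rose adjusted over the list alone, Hspa5 of the endoplasmic reticulum among them (0.44 ± 0.11; list adjusted p = 0.295 with an estimated correlation).

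Plxdc2, a transmembrane protein gene (ENSMUSG00000026748, chromosome 2, 16356304 to 16755839), stood at 91.3 ± 11.7 RPKM in the CNO libraries and 9.88 ± 1.69 in saline (8.51-fold, log2 3.09 ± 0.13, adjusted p = 2.47e-07). In the Chrm4 mice its unbound level ranged from 8.73 to 10.8 RPKM. Chrm3 itself rose from 2.70 ± 0.750 to 6.62 ± 0.567 RPKM (adjusted p = 0.0224). On the same chromosome as Plxdc2, Bmi1, a chromatin repressor, fell by 0.64 on the log2 scale (11.6 ± 0.784 against 18.7 ± 1.66 RPKM). Other falls were Xrcc3 of DNA repair (-1.11 ± 0.19), Zfp870 (-0.96 ± 0.16), Ccdc153 of ependymal cilia (-0.95 ± 0.18), Ankrd37 (-0.94 ± 0.19), the sulfite oxidase Suox (-0.87 ± 0.18), Zfp51 (-0.68 ± 0.14) and Rab9b (-0.61 ± 0.11).

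**Figure D3:**
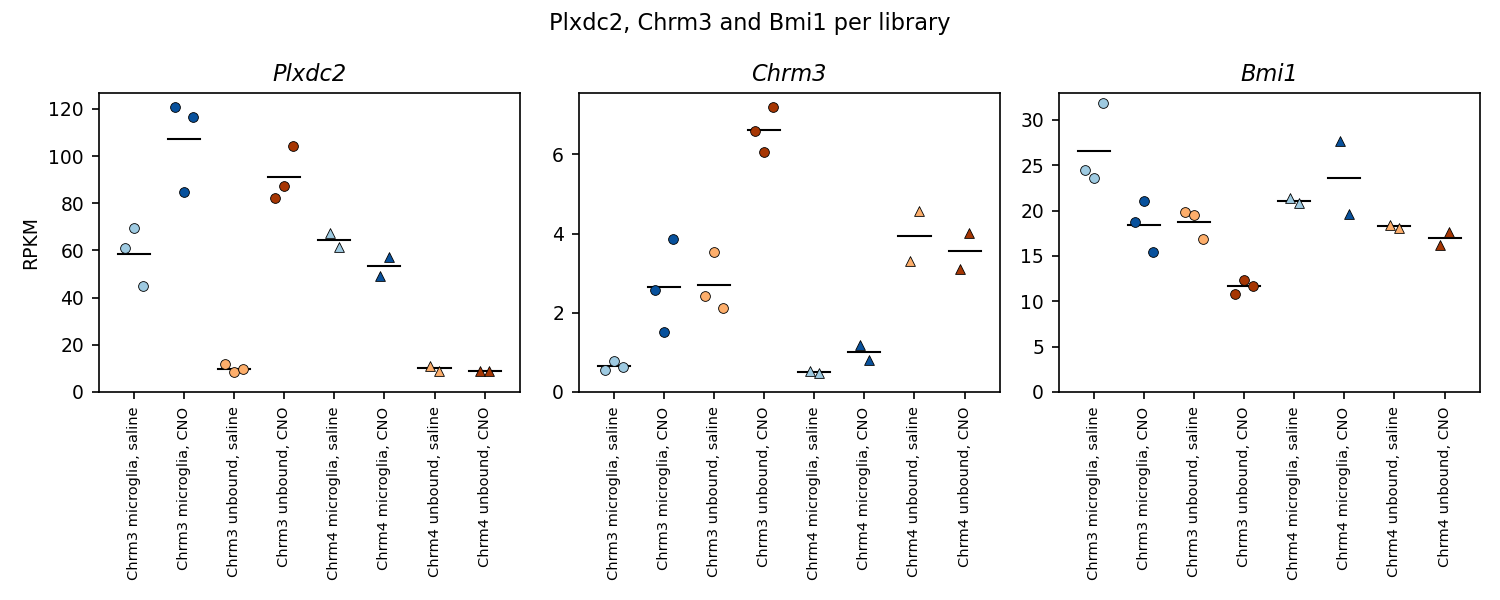
RPKM of Plxdc2, Chrm3 and Bmi1 in each library of 8 groups; circles are Chrm3 and triangles Chrm4 mice, blue the microglial pull-down, orange unbound RNA, light saline, dark CNO and lines the means. Plxdc2 in unbound RNA lies between 82.1 and 104 RPKM in the 3 Chrm3 CNO libraries and between 8.29 and 11.6 in saline.

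Markers of spiny projection neurons, the output cells of the striatum, fell in the same unbound libraries, though neither the pan-spiny nor the D2 list passed with an estimated correlation (adjusted p = 0.401 and 0.333 with an estimated correlation). All 14 pan-spiny markers were lower (median -0.49) and 9 fell adjusted over the list alone, among them Pde1b (-0.63 ± 0.15), Ppp1r1b (-0.63 ± 0.16) and Bcl11b (-0.48 ± 0.13). All 8 D2 markers were lower, and Gpr6 (-0.93 ± 0.21), Adora2a (-0.67 ± 0.19) and Drd2 (-0.46 ± 0.16) fell adjusted over the list alone. All 14 oligodendrocyte markers were lower (median -0.36; Opalin -0.68 ± 0.18, 1 of 3 that fell adjusted over the list alone), and so were 22 of 25 homeostatic microglia genes (median -0.31, none past the threshold) and 77 of 81 ribosomal protein genes (median -0.17), with adjusted p = 0.401, 0.333 and 0.607 with an estimated correlation. P2ry13 and Adora2a fell adjusted over the ATP and adenosine list alone, a list that did not pass (adjusted p = 0.0870). Cortical neuron markers, 7 of 8 higher (median 0.37; Slc17a7 0.50 ± 0.23), and pan-neuronal markers, 8 of 11 higher (Nefl 0.51 ± 0.11), rose as lists (adjusted p = 0.401 for both with an estimated correlation). Whether the opposite moves of spiny and cortical neuron markers came from CNO or from a difference in dissection was not tested. Glucocorticoid genes (5 higher and 1 lower, adjusted over the list alone) and NF-kB targets (2 higher) also rose as lists (adjusted p = 0.541 and 0.333 with an estimated correlation).

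Of 11123 genes 64 were higher and 14 lower, 1381 with an unadjusted p under 0.05. The count of 78 became 10, 62 and 8 without saline library 1, 2 or 3, and 115, 27 and 8 without CNO library 1, 2 or 3. Plxdc2 passed without any of them, and Egr2, Egr3, Fosl2, Bdnf and Nr4a3 did too. The other genes named here as passing were lost without at least 1 of these libraries other than CNO library 1 (adjusted p = 0.0553 to 0.207), and Ccdc153, Ankrd37 and Zfp51 also without that one (0.0871 to 0.0915). Saline library 1 held pituitary hormone RNA (Prl at 4.83 and Gh at 6.39 RPKM), and a class of sequencing depth as a covariate left 36 genes. Of the lists, activity, heat shock, D2, pan-spiny and oligodendrocyte passed without any library. Glucocorticoid genes were lost without saline library 2 or 3 or CNO library 2 or 3 (up to 0.208), pan-neuronal markers without saline library 1 or 3 or CNO library 1 (up to 0.147) and cortical markers without saline library 1 or CNO library 1 (up to 0.147). NF-kB targets were lost without saline library 2 (0.0579), homeostatic genes without CNO library 1 (0.0970) and ribosomal genes without CNO library 3 (0.0610).

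What did Chrm4 silencing do to the unbound RNA? No gene passed, while markers of D2 neurons fell as a list that did not pass with an estimated correlation (adjusted p = 0.340 with an estimated correlation). Penk stood at 287 ± 38.1 RPKM after CNO and 505 ± 78.4 after saline (SD, n = 2 each; -0.81 ± 0.23), and the dopamine receptor Drd2 at 54.9 ± 8.72 against 81.7 ± 12.5. Both fell adjusted over the D2 list alone, all 8 members of which were lower (median -0.29), and Ptpn5, a striatal phosphatase (-0.64 ± 0.17), fell adjusted over the pan-spiny list alone, where 13 of 14 were lower, Ppp1r1b (-0.45 ± 0.19) and Gng7 (-0.64 ± 0.21) among them (list adjusted p = 0.728 with an estimated correlation). Activity genes fell as a list, 22 of 30 lower with a median of -0.25 and none past the threshold (adjusted p = 0.864 with an estimated correlation), for instance Inhba (16.2 ± 6.43 against 30.4 ± 2.48 RPKM), Egr3 (16.3 ± 2.09 against 23.4 ± 3.94), Nr4a1 (7.83 ± 2.96 against 14.9 ± 2.20) and Fos (1.71 ± 1.55 against 2.61 ± 0.611). Complement (5 of 5 lower), potassium channel (19 of 22) and cAMP signalling genes (17 of 24) fell, and ribosomal protein genes (60 of 81 higher; Rps13 0.39 ± 0.13) and ependymal markers rose. For these 5 lists adjusted p = 0.340 to 0.882 with an estimated correlation.

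Ttr, at 159 ± 178 against 7.92 ± 2.21 RPKM, rose adjusted over the ependymal list alone, and 1 CNO library held 284.6 RPKM of it. Hbb-b1, a haemoglobin chain, rose adjusted over the blood cell list alone (10.8 ± 0.406 against 6.03 ± 0.792), a list that did not pass. Adora2a was at 25.7 ± 4.85 against 33.0 ± 10.9 and Chrm4 at 3.83 ± 0.783 against 4.59 ± 0.637. By limma 0 of 11123 genes passed and 559 had an unadjusted p under 0.05 (voom 0 and 482), and without CNO library 1 there were 3, Ttr among them (adjusted p = 0.00880). Both CNO libraries were far deeper than both saline libraries. With a class of depth as a covariate, which rests on the Chrm3 libraries of both classes in the same fit, the ependymal (adjusted p = 0.310) and complement lists (0.287) were lost and the other 6 kept. The D2 and pan-spiny lists fell after CNO in unbound RNA of both lines, whose receptors are of opposite kinds. The D2 list passed without any library. Lost were activity genes without saline library 1 or 2 or CNO library 2 (up to 0.714), pan-spiny, cAMP and complement genes without saline library 1 or CNO library 1 (up to 0.580, 0.736 and 0.580), ribosomal genes without saline library 1 or CNO library 2 (up to 0.602), and ependymal and potassium channel genes without saline library 2 or CNO library 2 (up to 0.610 and 0.508).

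Did the Chrm3 response differ between microglial and unbound RNA? Plxdc2 was the 1 gene whose change differed, being smaller in the microglial pull-down by -2.22 ± 0.25 on the log2 scale (adjusted p = 0.000313). There it stood at 107 ± 19.8 RPKM after CNO and 58.5 ± 12.5 after saline (SD, n = 3 each). In unbound RNA it was at 91.3 ± 11.7 and 9.88 ± 1.69. The saline pull-down began from a higher level, so the smaller log2 change does not show a weaker response of microglia. The same holds for Dusp6, at 94.4 RPKM in the saline pull-down and 8.02 in saline unbound RNA. Activity genes changed less in microglia as a list (23 of 32 negative, median -0.42; adjusted p = 0.948 with an estimated correlation), with Dusp6, a phosphatase of the MAP kinase ERK, passing adjusted over the list alone (-1.93 ± 0.46) and Fosl2 at -1.22 ± 0.41. Chemokine genes changed more (13 of 19 positive, median 0.35; adjusted p = 0.948 with an estimated correlation). Ccl4 passed adjusted over the list alone (1.95 ± 0.45), and Ccl2 (2.07 ± 0.71) and Ccl3 (1.45 ± 0.63) did not. Homeostatic microglia genes were more positive in 28 of 30 cases (median 0.29; adjusted p = 0.948 with an estimated correlation), for instance Csf1r (0.66 ± 0.27) and Tmem119 (0.55 ± 0.25), none past the threshold. Of 11721 genes 477 had an unadjusted p under 0.05. The count of 1 became 2 without pull-down CNO library 1 or 2, and 3 without unbound CNO library 1, where Dusp6 passed (adjusted p = 0.00473). The chemokine list was lost without pull-down saline library 2 or 3, pull-down CNO library 2, unbound saline library 1 or 2 or unbound CNO library 1 or 2 (up to 0.544), homeostatic genes without pull-down saline library 3 (0.334) and activity genes without pull-down CNO library 1 or unbound CNO library 2 (up to 0.535).

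Which RNAs did the D1 pull-down enrich? Genes of D1 neurons, the spiny neurons of the direct pathway, rose against the unbound RNA of control mice. Genes of D2 neurons, interneurons and glia fell. Over all genes the median log2 change was 0.81 as deposited, and the rises given here include that shift. The dopamine receptor Drd1a stood at 152 ± 16.3 against 32.7 ± 3.50 RPKM (SD, n = 4 each; 4.54-fold), the substance P precursor Tac1 at 804 ± 56.2 against 131 ± 17.1 (6.14-fold), Slc35d3 at 30.9 ± 4.18 against 5.39 ± 1.30 and the muscarinic receptor Chrm4 at 15.9 ± 3.25 against 3.50 ± 0.604. All 9 D1 markers rose, but relative to other genes the list did not pass (adjusted p = 0.0812). The calmodulin regulator Pcp4 was at 2593 ± 425 against 525 ± 72.7, and the nuclear genes Yeats2 (10.1-fold), Gtf2i (6.33-fold) and Arid1b (5.36-fold) were among the largest rises. Il34, a ligand of Csf1r made by neurons, rose 2.58-fold to 9.03 ± 1.73 RPKM. Penk (0.363 of the unbound level), Drd2 (0.342), Adora2a (0.313) and Gpr6 (0.451) fell, with all 7 D2 markers lower and 6 past the threshold. The interneuron factor Lhx6 fell to 0.449, with 8 of 9 interneuron markers.

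Myelin and astrocyte genes fell, such as Mog (0.262 of the unbound level), Slc1a3 (0.308) and the gap junction gene Gja1 (0.286), with 14 of 14 oligodendrocyte and 13 of 14 astrocyte markers. Microglial RNA was at a low level, with C1qb at 2.03 ± 0.533 against 10.7 ± 1.31 and P2ry12 at 1.15 ± 0.401 against 5.84 ± 0.572, and 16 of 17 homeostatic genes fell. The oligodendrocyte precursor (5 of 6), ependymal (3 of 5) and disease-associated (6 of 11) lists fell too. These lists passed with an estimated correlation (adjusted p = 0.00122 to 0.0226), as did the ATP and adenosine list (0.0130), which was lost with quantile scaling, median-ratio scaling and voom (0.107, 0.130 and 0.0592). Transcripts of the mitochondrial genome fell most, mt-Co1 from 7916 ± 315 to 537 ± 178, mt-Nd1 to 0.0749 and mt-Cytb to 0.0777 of the unbound level. Mitochondrial genes took 0.216% to 0.674% of the reads in D1 pull-downs and 5.76% to 8.92% in the unbound RNA. In the table of the Chrm3 and Chrm4 mice they took 0% in every library. The reason is not stated, so this is not read as a level of these RNAs. Nuclear genes of the respiratory chain rose in 72 of 73 cases (Ndufs4 3.26-fold; list adjusted p = 0.529 with an estimated correlation), and all 80 ribosomal protein genes were called higher (median 0.87, close to that of all genes; Rpl27a 2.43-fold) in a list that did not pass (adjusted p = 0.0812). Glucocorticoid, interferon and motility lists fell relative to other genes (adjusted p = 0.266, 0.136 and 0.159 with an estimated correlation), although the medians of the first and last were 0.15 and 0.06, and the interferon list was lost with quantile or median-ratio scaling (0.0796 and 0.0629). Of 10266 genes 8710 were higher and 702 lower. The median of all genes was 0.81 as deposited, 0.10 with quantile scaling (3609 higher and 2291 lower) and -0.05 with median-ratio scaling (1984 and 3251).

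Did D1 neurons differ between animals labelled Il34 knockout and control? Flrt2, a membrane protein of axon guidance and adhesion (ENSMUSG00000047414, chromosome 12, 95692226 to 95785215), was the 1 gene that passed. It stood at 20.8 ± 4.74 RPKM (SD, n = 3) against 8.04 ± 0.496 (n = 4), 2.38-fold higher (log2 1.25 ± 0.13, adjusted p = 0.0224), with all 3 libraries above all controls. Il34 itself was not lower, at 10.3 ± 0.704 against 9.03 ± 1.73 RPKM (95% interval of log2 -0.13 to 0.50), and the source label reads Il34-/- for the controls as well, so the labels are used here only as names. Ribosomal protein genes rose as a list, 79 of 80 higher by a median of 0.15 (adjusted p = 0.862 with an estimated correlation; Rpl23a 22.4 ± 2.99 against 16.7 ± 1.96, Rplp0 41.9 ± 8.57 against 33.3 ± 2.01), and so did respiratory chain genes (56 of 73, median 0.08; adjusted p = 0.862 with an estimated correlation; Ndufb11 110 ± 15.5 against 94.8 ± 5.16) and astrocyte markers (12 of 13, median 0.20; adjusted p = 0.862 with an estimated correlation; Mlc1 4.03 ± 0.477 against 2.87 ± 0.632, Acsbg1 3.95 ± 0.395 against 3.06 ± 0.259). GABA receptor genes fell (9 of 14, median -0.09; adjusted p = 0.862 with an estimated correlation; Gabra2 16.9 ± 2.02 against 25.3 ± 6.71). No member of these 4 lists passed over all genes or adjusted over the list alone.

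Genes of D1 neuron identity did not pass. Drd1a was at 187 ± 77.0 against 152 ± 16.3 RPKM, with 1 library at 275, Pde10a at 224 ± 18.3 against 242 ± 17.5, Snap25 at 1244 ± 54.3 against 1390 ± 134, Chrm4 at 16.3 ± 1.54 against 15.9 ± 3.25 and Adora1 at 25.1 ± 2.26 against 24.5 ± 3.06. Npas4 was at 5.47 ± 3.39 against 2.32 ± 2.84, the lipid carrier Apoe at 23.1 ± 4.36 against 15.5 ± 4.93 and Tyrobp at 2.21 ± 0.603 against 3.11 ± 0.676. Of 10452 genes 160 had an unadjusted p under 0.05. Flrt2 was lost without any 1 of the 4 controls or knockout library 1 (adjusted p = 0.0947 to 0.151), each leaving a count of 0. The ribosomal list passed without any library, and the others were lost without control library 4 or knockout library 1, GABA receptors up to 0.191, astrocyte markers up to 0.185 and the respiratory chain up to 0.974.

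Did the unbound striatal RNA differ between these animals? Genes of microglia were lower in the libraries labelled knockout, although no single gene passed over all genes. P2ry12 stood at 3.00 ± 0.999 RPKM against 5.84 ± 0.572 (SD, n = 4 each; log2 -0.81 ± 0.16), Siglech lower by a log2 of -0.55 ± 0.10, Tmem119 at 1.11 ± 0.199 against 2.03 ± 0.383, Selplg at 1.02 ± 0.252 against 1.93 ± 0.312, Csf1r at 1.84 ± 0.442 against 2.95 ± 0.330 and Cx3cr1 at 0.971 ± 0.316 against 1.89 ± 0.445. For each of these 6 genes all 4 libraries lay below all 4 controls. All 25 homeostatic microglia genes were lower (median -0.49 ± 0.16), 0 past the threshold over all genes and 21 adjusted over the list alone, among them Aif1 (-0.50 ± 0.14), P2ry13 (-0.55 ± 0.14), Itgam (-0.44 ± 0.11), C1qb (-0.58 ± 0.18) and C1qc (-0.38 ± 0.14). The list passed with an estimated correlation (adjusted p = 0.0309). The mean log2 level over the list was lower by 0.444 (exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 allows, not adjusted for the choice of this list).

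**Figure D4:**
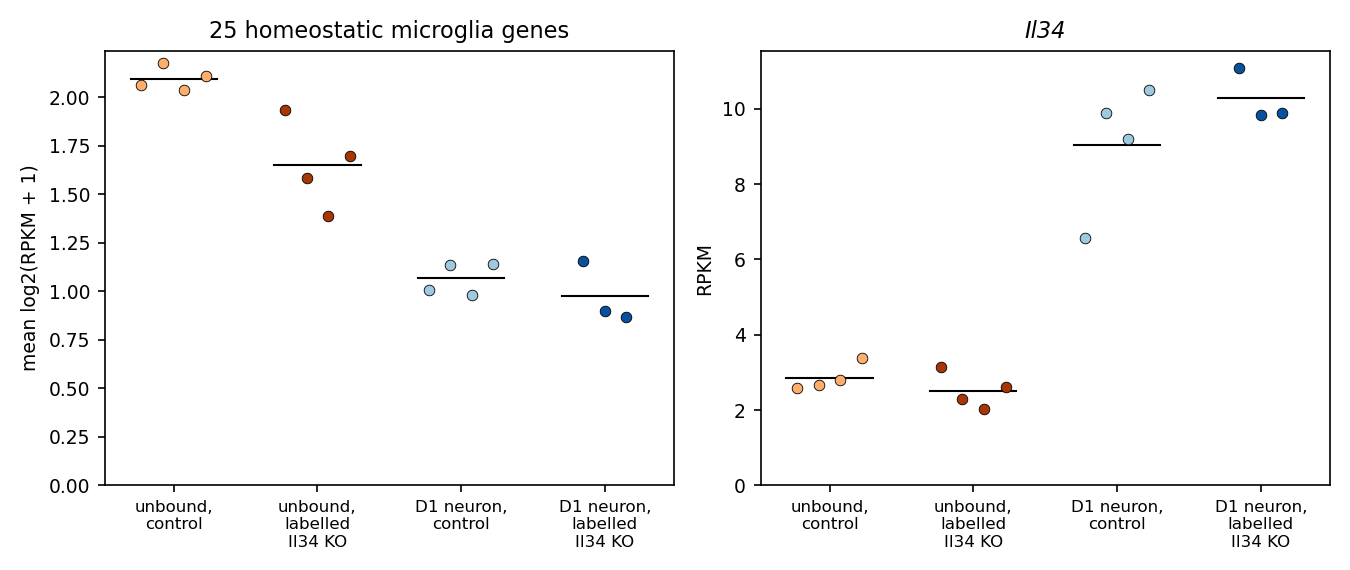
Mean log2(RPKM + 1) of 25 homeostatic microglia genes (left) and RPKM of Il34 (right) in each library of the 4 groups of the D1 line; lines are means. Every unbound library labelled knockout lies below every unbound control on the left, by 0.444 on average, and Il34 is at 2.51 and 2.85 RPKM on the right.

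The ATP and adenosine list fell (9 of 9 lower; P2ry12 and P2ry13 adjusted over the list alone) and passed with an estimated correlation (adjusted p = 0.0309), but was lost with no minimum (0.273) and with array weights (0.0634). The motility list fell (11 of 11 lower; Itgam alone adjusted over the list, Wasf2 -0.21 ± 0.09), with adjusted p = 0.718 with an estimated correlation. Lists of neurons, astrocytes and oligodendrocytes did not pass, with the exception of D2 markers (7 of 7 lower, median -0.14; Gpr6 10.3 ± 1.02 against 12.1 ± 1.76), just under the threshold (0.954 as adjusted p with an estimated correlation). Il34 was at 2.51 ± 0.481 against 2.85 ± 0.360 RPKM, the other Csf1r ligand Csf1 at 1.31 ± 0.339 against 1.36 ± 0.243, Entpd1 at 1.66 ± 0.212 against 1.99 ± 0.478, Nt5e at 2.58 ± 0.993 against 3.12 ± 0.805, Adora2a at 14.3 ± 4.12 against 16.6 ± 4.65, Drd1a at 40.2 ± 12.1 against 32.7 ± 3.50 and Drd2 at 72.0 ± 12.5 against 75.3 ± 12.6. By limma 0 of 9853 genes passed and 87 had an unadjusted p under 0.05 (voom 0 and 87), fewer than the 493 that chance gives. With array weights, which count deviating libraries less, 27 passed, all lower, Siglech and P2ry12 (both adjusted p = 0.0117) among them. Without knockout library 2 the count was 1. Homeostatic and motility genes passed without any library, the ATP list was lost without control library 4 (0.299), and D2 markers were lost without control library 3 or 4 or knockout library 1 (up to 0.975).

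Did these changes differ between D1 neurons and unbound RNA? Homeostatic microglia genes changed less negatively in the D1 pull-down, in 17 of 17 cases by a median of 0.32, for instance Tmem119 (0.55 ± 0.17), Tgfbr1 (0.32 ± 0.11), P2ry12 (0.56 ± 0.25) and Csf1r (0.34 ± 0.16). Ribosomal protein genes (78 of 80 positive, median 0.20; Rplp0 0.39 ± 0.17) and astrocyte markers (12 of 14, median 0.15; Acsbg1 0.34 ± 0.12) were more positive there. No member passed over all genes or adjusted over the list alone, and the 3 lists had adjusted p = 0.756 to 0.934 with an estimated correlation. By limma 0 of 10266 genes passed and 100 had an unadjusted p under 0.05 (voom 0 and 106). Astrocyte markers were lost without pull-down control library 3 or 4, unbound control library 2, pull-down knockout library 1 or unbound knockout library 4 (up to 0.381).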

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

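The tests of explanations in this part were chosen after the results were seen, including the distance around Plxdc2, the carry-over of neuronal RNA and the share of microglial RNA. The comparisons between 2 changes and the rule for single deviating libraries were fixed in advance.

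The rise of activity genes in the microglial pull-down after Chrm3 activation may come from neuronal RNA carried into it. For the 28 of 33 activity genes that gained at least 5 RPKM in unbound RNA, the RPKM gained in the pull-down was a median 34.9% of that gain (34.9% also for the 31 genes at a mean of at least 1 RPKM there), and 33 neuronal markers stood in the saline pull-down at a median 37.1% of their unbound level (22.2% to 46.3% from the 10th to the 90th percentile, with Nefl at 230%). Depth classes were balanced, with 1 deep and 2 shallow pull-down libraries in each of the CNO and saline groups. Between the shallow libraries alone the 5 called genes differed by a median log2 of 2.91. These genes were picked for their separation over all libraries, so this cannot decide on depth for the list. The tables argue against carry-over for Ccl2, Ccl3, Ccl4 and Ccl7. Their gain in the pull-down was at least 6.14 times their whole level in unbound RNA after CNO. Of the 28 genes 8 lay above the 90th percentile of the markers, Ier5 (177%), Btg2 (176%), Jun (123%), Dusp1 (80.5%), Inhba (71.8%), Egr2 (58.5%), Npas4 (49.6%) and Atf3 (46.4%), and of the 5 genes left out Ier2 and Klf2 gained more in the pull-down than in unbound RNA. A response of microglia themselves stays open for the chemokines and for these genes, but least for Npas4, which is neuron-specific. Npas4 and Atf3 also lay below the neuronal marker Gng7 (52.4%), and all 8 lay below the neuronal marker Nefl (230%). The shares alone therefore do not set any of the 8 apart from carry-over.

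Plxdc2 and Chrm3 were both higher in the CNO animals of the Chrm3 line, and a candidate explanation is that the receptor transgene was carried by those animals alone. In unbound RNA the saline animals of that line had less Chrm3 than the Chrm4 line, with a log2 ratio of -0.48 ± 0.26 (2.70 ± 0.750 RPKM, n = 3, against 3.75 ± 0.671, n = 4; exact permutation p = 0.143). This cannot decide it, since whether reads of the transgene count towards the mouse gene was not tested. In unbound RNA, Chrm4 stood at 4.59 ± 0.637 (saline) and 3.83 ± 0.783 RPKM (CNO) in the Chrm4 line. It was at 4.09 ± 0.644 in saline animals of the Chrm3 line, so no excess marked the line with that receptor. Activity cannot be told apart from a transgene of the CNO animals alone. The rise of Plxdc2 in unbound CNO library 1 was 84.0% of that in the other CNO libraries. The activity genes there rose by a median 25.1%, which is 1 library. A change of the region around Plxdc2 cannot be told apart either, with 2 of 29 genes within 5 Mb at an unadjusted p under 0.001 against 122 of 10967 elsewhere (Fisher's exact p = 0.0420, and 0.00773 within 2.5 Mb and 0.224 within 10 Mb). Genotypes were not analysed here, and such a difference would run through every comparison of CNO with saline in the Chrm3 line.

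Microglial genes were lower in the unbound libraries labelled Il34 knockout, and a smaller share of microglial RNA in the tissue is a candidate explanation. Of the 44 measured genes at least 32-fold higher in the microglial pull-down, 100% were lower (44 of 44, median log2 ratio -0.58), and so were the 21 of them outside the lists that fell (21 of 21, -0.46; the ratios here are of RPKM without the 1 added in the fits, which give a median of -0.49 for the homeostatic and -0.14 for the D2 list). A difference in dissection stays open, as endothelial markers (1 measured gene) had a ratio of -0.26 and no other list of another cell type moved further than D2 markers (-0.16), against -0.69 for the homeostatic genes, but 2 of 4 unbound knockout libraries and 0 of 4 controls held pituitary hormone RNA. Without these 2 the homeostatic list still passed. These 2 were the only female libraries of that group by Ddx3y, so leaving them out also changed the balance of sex. The tables argue against a loss of Il34 RNA by over 1 on the log2 scale, as it changed by -0.14 in the fit (95% interval -0.37 to 0.10) and by 0.18 in D1 neurons (-0.13 to 0.50), while a loss of function that leaves the RNA and a lower level per cell stay open.

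Other splits of the same libraries were counted for comparisons of at least 3 against 3. For the mean of the homeostatic genes the real split gave a difference of 0.444, the highest of 35 for this list (next 0.395). The list was taken up because it fell, and in 17 of 35 splits some list of the 24 differed as much (up to 1.10, cortical markers), so chance cannot be excluded. The pull-downs differed from unbound RNA in more genes than in any other split, 7633 against 4772 for microglia (1 of 60) and 9412 against 0 for D1 neurons (1 of 35). For Chrm3 microglia (5 genes, highest other 1; 1 of 10) and unbound RNA (78, highest other 0; 1 of 10) the splits are too few for a share under 0.05. Chance cannot be excluded for the count of 1 in D1 neurons (7 of 35 splits gave as many, up to 14). Splits decide nothing about the counts of 0 in unbound RNA of that line (35 of 35, up to 4; limma, 87 genes at an unadjusted p under 0.05, voom 0) and in its comparison with D1 neurons (100 of 100, up to 1; limma, 100 genes, voom 0), since no split can give fewer. Nor do they for the count of 1 between the Chrm3 fractions (31 of 100, up to 91), since splits that exchange CNO and saline in 1 fraction still hold the effect of CNO.

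In the pull-downs, the responses to CNO differed between Chrm3 and Chrm4 mice by a test of the difference. This held for activity (median log2 1.27), heat shock (0.34), glucocorticoid (0.43), chemokine (0.32) and astrocyte genes (-0.42). All were lost with an estimated correlation (adjusted p = 0.209 to 0.748 with an estimated correlation), and carry-over stays open for the activity genes. The Chrm3 responses differed between pull-down and unbound RNA for Plxdc2 (-2.22) and for activity (-0.42), homeostatic (0.29) and chemokine genes (0.35). These 3 lists had adjusted p = 0.948 each with an estimated correlation. The chemokine list passed in 5 of 12 fits with 1 library left out. Ccl2, Ccl3 and Ccl4 of this list were at a low level in unbound RNA, where the added 1 RPKM shrinks log2 changes. The changes with the Il34 label differed between D1 neurons and unbound RNA for homeostatic (0.32), astrocyte (0.15) and ribosomal protein genes (0.20), none of which passed with an estimated correlation (adjusted p = 0.756 to 0.934 with an estimated correlation). Homeostatic genes were at a low level in the D1 pull-down, where the added 1 RPKM shrinks log2 changes. Single libraries far from the others of their group were Npas4 at 6.57 RPKM in D1 control pull-down library 4 (others 0.645 to 1.22), Ctsz at 4.59 in unbound knockout library 1 (3.29 to 3.32), Tgfbr1 at 2.56 in unbound control library 4 (2.34 to 2.38) and Lhx6 at 4.75 in unbound control library 3 (4.36 to 4.38). These are 4 of 112 groups, where chance alone gives 1 in 20, or 5.6.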

How the results depend on the processing

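Voom, the class of depth, sex, the libraries with pituitary RNA and the list tests under each setting were chosen after the data were seen. No paired analysis was possible because the columns carry no replicate numbers, and the planned replicate block alternatives were not run. Sex by Ddx3y was the same in both fractions at each place within a group, but the labels do not say that libraries of 1 place share an animal. With a group of 2, leaving out 1 library assumes that the lone one varies like the other groups.

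Of 2043 values of named genes under alternatives, 1923 kept direction and side of the threshold, 91 lost the call, 21 gained one and 8 reversed, and none of the 890 past the threshold reversed. With 1 library left out, 1404 of 1550 kept both, 110 lost the call, 13 gained one and 23 reversed. Of 90 list calls 16 held with an estimated correlation and 77 on ranks. Under other alternatives 804 of 887 list results held and 1 reversed, and with 1 library left out 622 of 711 held and 3 reversed.

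For Chrm3 microglia (5 genes) no minimum gave 1, array weights 3, only the compared groups 8 and voom 18, and leaving out libraries 0 to 35. For Chrm3 unbound RNA (78) no minimum gave 1, array weights 125, only the compared groups 30, voom 127, the class of depth 36 and leaving out the library with pituitary RNA 10, and leaving out libraries 8 to 115. No minimum gave 2 for Chrm4 unbound RNA (0; 0 to 3 with a library left out) and 0 for D1 neurons (1; 0 to 1; limma, voom 1). Array weights gave 27 for unbound RNA of the D1 line (0; 0 to 1), and the difference of Chrm3 and Chrm4 ran from 0 to 12, that between Chrm3 fractions from 1 to 3. For D1 pull-down against unbound RNA (9412) a minimum of 5 RPKM gave 5867, as fewer genes were tested, quantile scaling 5900, median-ratio scaling 5235 and voom 6044. The cause was not tested for the other changes.

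Reversed log2 changes, none past the threshold, were Cx3cr1 with quantile scaling (-0.0027) and array weights (-0.0099), P2ry12 (-0.027) and Entpd1 (-0.083) with array weights in Chrm3 microglia, Chrm4 in Chrm4 microglia with a pseudocount of 0.1 (0.0030) and voom (0.011), and in unbound RNA of the D1 line Drd2 with array weights (0.0097) and Csf1 without the libraries with pituitary RNA (0.071), with the D2 list at adjusted p = 0.858 with array weights.

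With 1 library left out, these log2 changes crossed 0, none past the threshold. In Chrm3 microglia P2ry12 ran from -0.181 to 0.18, Entpd1 from -0.129 to 0.316, Csf1r from -0.0608 to 0.263 and Cx3cr1 from -0.115 to 0.177, lowest without saline library 3 and highest without saline library 1 or 2. In Chrm4 microglia Fos ran from -0.225 to 0.0615, P2ry12 from -0.121 to 0.0738, Chrm4 from -0.751 to 0.622 and Csf1r from -0.103 to 0.404, the ends being those without saline library 1 or 2. In Chrm4 unbound RNA Fos ran from -1.15 (without CNO library 1) to 0.0848 (CNO library 2) and Adora2a from -0.656 (saline library 2) to 0.00773 (saline library 1). In D1 neurons Drd1a ran from -0.0879 (knockout library 2) to 0.424 (knockout library 1), Chrm4 from -0.0686 (control library 1) to 0.161 (control library 4) and Adora1 from -0.0295 (knockout library 1) to 0.102 (control library 4). In unbound RNA of that line Csf1 ran from -0.133 (knockout library 1) to 0.0224 (knockout library 4) and Drd2 from -0.185 (control library 1) to 0.0491 (knockout library 1). The respiratory chain list in D1 neurons had adjusted p = 2.29e-07 (without knockout library 3) to 0.974 (knockout library 1), and the D2 list in unbound RNA 6.00e-06 (control library 1) to 0.975 (control library 4), both turning direction at the upper end.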

Other observations

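In the pull-down of saline mice activity genes went both ways. Dusp6, a phosphatase of ERK, was 9.25-fold higher in microglia than in unbound RNA (log2 3.21 ± 0.26, n = 5 each), and Egr3 was at 0.206 of its unbound level (log2 -2.28 ± 0.22). Of 32 activity genes 8 were higher and 14 lower, and the list did not pass (adjusted p = 0.211). Over all 11721 genes 3743 were higher and 3890 lower, so this is nothing particular to activity genes.

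The gene that passed in D1 neurons was also measured in unbound RNA of the same line. Flrt2 was there at 8.15 ± 2.19 RPKM in libraries labelled knockout and 5.59 ± 0.547 in controls (SD, n = 4 each), with unbound knockout library 3 at 5.85.

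The following were chosen after their values were seen and are given as values. RNA of the pituitary hormones prolactin (Prl) and growth hormone (Gh) stood at 4.83 and 6.39 RPKM in Chrm3 unbound saline library 1, 1.72 and 2.45 in D1 knockout pull-down library 3, 4.27 and 2.28 in unbound knockout library 3, and 9.37 and 10.99 in unbound knockout library 4. Eya1 was at 2.32 RPKM in unbound knockout library 3, 28.2 to 42.2 in the other 7 unbound libraries of the line, 124 to 190 in D1 pull-downs and 3.02 to 5.57 in the unbound RNA of the Chrm3 and Chrm4 mice. Among the unbound libraries of the line, knockout library 3 also had the lowest mean log2 level of the homeostatic genes (1.39). Their list passed without it. Arl5b, near Plxdc2 on chromosome 2, had a log2 change of 1.33 in Chrm3 unbound RNA (adjusted p = 0.0195).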
